A study of Homo sapiens with 18 samples.

How the data were processed

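Total RNA from MCF10A derivatives was made into 18 libraries with a total-RNA kit that depletes ribosomal RNA, per the labels' protocols. The cells grew with 5% horse serum and 20 ng/ml EGF. The design text gives 6 lines in triplicate, and groups and replicate numbers were taken from the sample titles. The labels do not say whether the 3 libraries of a line came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Descriptions carry a 6-digit code, 061218 for replicates 1 and 2 and 071818 for replicate 3, whose meaning is not given; 071818 holds 1 library per line and was not tested alone.

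The main input was the authors' deposited table of read counts per gene, 58288 genes by 18 libraries, unnormalized. The submitters' processing notes name STAR 2.7, edgeR 3.8 and the hg38/GRCh38 build. The strand setting of the counting and the annotation release are not given in the sources used here. Without strand, reads of overlapping or antisense genes cannot be told apart, and genes with near-identical relatives or pseudogenes (HSD3B1, keratins, ribosomal protein genes) are uncertain. A further 4 summary rows per library name no gene and were left out of library sizes and tests; of all reads they hold 2.67% to 5.44% outside features, 6.08% to 7.15% mapping to several places, 6.80% to 7.53% ambiguous and 1.97% to 3.78% unmapped. A second deposited table holds scaled values, treated as signal; per the submitters' notes and the values, each column equals the authors' counts divided by 1 constant per library (largest relative deviation 2.1e-15). Its 765 repeated rows were dropped and the table was used in an alternative only; its columns sum to 962737 to 1050504 with the summary rows kept. Symbols and coordinates came from GENCODE release 44 on GRCh38, in which 57577 of the gene identifiers were found.

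Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which kept 14961 and dropped 43327, 25807 of them with 0 reads in every library. The rest were scaled by TMM and fitted by edgeR 4.0.16 with the quasi-likelihood test, using 1 mean per line over all 18 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 20.4%. Contrasts were YAP against YAPS94A within each hairpin, each AIB1 hairpin against shGFP within each line, hairpin 2 against hairpin 1, and the interaction. A hairpin effect counted only if both hairpins were called in 1 direction. Standard errors were the absolute log2 fold change over the square root of F. Libraries held 14482437 to 21368384 gene reads, so counting error is small for genes above a few CPM; intervals for genes with few reads cover counting error only. No replicate pair had counts that agreed within sampling noise (chi-square per degree of freedom 29.4 to 131).

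Samples with the same replicate number deviated together: correlations of deviations from the line means were 0.379 to 0.658 for number 1, 0.136 to 0.431 for number 2 and 0.431 to 0.704 for number 3, all above 0.1. The numbers were therefore taken to pair the libraries, and the fit with the replicate number as a block is printed where it changes a call or moves a count by over 1.5 times.

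Before the data were examined, 29 gene lists were fixed: YAP/TEAD targets, Hippo components, p160 coactivators, mesenchymal, epithelial junction, basal, squamous, luminal, G2/M, S phase, interferon, NF-kB, EGF family, extracellular matrix, cholesterol, glycolysis, p53, stress response, TGF-beta, Notch, Wnt, actin, ribosomal protein, mitochondrially encoded, histone, immediate early stress, fibroblast, endothelial and leukocyte genes. NCOA3 and YAP1 were kept out of the lists. Each list was tested with camera (limma 3.58.1; preset correlation 0.01), adjusted over the 29 lists within a contrast, and with an estimated correlation. In the lists, a member counted as called for the hairpins was called with both in 1 direction, also where p was adjusted over the list alone. The named genes were also fixed by rule: NCOA3, YAP1 and 10 genes of general interest, the 8 largest rises and falls per main comparison among called genes with a mean of at least 2 CPM and no overlap between the groups' libraries, which 1 of the 10 splits of 6 libraries gives by chance, and up to 5 called members per list with the largest change. Some genes under this rule are not reported here.

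All 18 libraries, the shared controls included, were simulated 20 times with no gene changed. Each simulated library was drawn independently, here and below, so the pairing by replicate number was absent. Simulated correlations, covariances and shares of genes called therefore hold for unpaired libraries fitted without a block. On simulated counts with known changes, the construct contrast called 12.3%, 56.7% and 87.9% of genes changed by 1.5-fold, 2-fold and 4-fold (14691 genes), and the both-hairpin rule 13.8%, 41.8% and 78.1% (14711 genes). The search of 3′ UTRs for 7-mers covered 12566 genes with an annotated 3′ UTR, in 20 length bins with 1000 random sets, and left out 7-mers expected in under 3 genes of a set. Alternatives tried were DESeq2 1.42.0, its size factors, limma-voom, other filters, a block for the replicate number or the description code, only the groups compared, single libraries left out, a fold threshold, limma on the deposited scaled values with a pseudocount of 1 or 0.1, fry, and, added after the data were seen, the 061218 libraries alone and overlaps without a shared library. The fits with a single library left out had no block. R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.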

Results

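RNA was sequenced from 6 derivatives of MCF10A, an immortalized, non-tumorigenic human mammary epithelial cell line, with 3 libraries per derivative and 18 in all. Each derivative carried YAP, the transcriptional coactivator held back by the Hippo pathway, or YAPS94A, a form with a serine-to-alanine change that impairs binding to TEAD transcription factors. Each also carried a hairpin: shGFP as control, or shAIB1#1 or shAIB1#2 (here hairpin 1 and hairpin 2) against AIB1, a p160 steroid receptor coactivator encoded by NCOA3. The cells were at passage 10 to 15. Between 14482437 and 21368384 reads per library were assigned to genes, and 14961 genes were tested. Levels are given as CPM, read counts scaled by library size, as mean ± SD of 3 libraries, and log2 fold changes as estimate ± standard error from the edgeR quasi-likelihood fit, with Benjamini-Hochberg adjusted p. Of the variance in the first principal component (28.7% of the total), 43.8% lay between replicate numbers and 39.1% between hairpins. In the second (19.3%), 71.6% lay between the constructs.

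NCOA3 (ENSG00000124151.18, chromosome 20, 47501887 to 47656877, plus strand, GRCh38), the gene both AIB1 hairpins target, was lower in every AIB1 hairpin library than in every shGFP library of its line. With shGFP, replicates 1 to 3 held 154, 167 and 132 CPM in the YAP line and 188, 146 and 122 CPM in the YAPS94A line. Hairpin 1 left 59.4, 75.8 and 61.9 CPM with YAP and 61.4, 61.0 and 61.5 CPM with YAPS94A. Hairpin 2 left 88.5, 112 and 88.6 CPM with YAP and 82.5, 83.4 and 76.8 CPM with YAPS94A. In the YAP line the log2 fold change was −1.20 ± 0.15 with hairpin 1 (adjusted p = 0.000225) and −0.65 ± 0.15 with hairpin 2 (adjusted p = 0.0128). In the YAPS94A line it was −1.31 ± 0.15 (adjusted p = 6.52e-05) and −0.91 ± 0.15 (adjusted p = 0.00139). In fits that, like the main one, had no replicate block, the call for hairpin 2 in the YAP line ended without YAP-shGFP replicate 2 (adjusted p = 0.0577) or YAP-shAIB1#2 replicate 1 (adjusted p = 0.0615). Between the constructs with shGFP, NCOA3 differed by −0.01 ± 0.15 (adjusted p = 0.987).

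YAP1 (ENSG00000137693.13, chromosome 11, 102110447 to 102233424, plus strand), whose reads come from the cell's own gene and may include those of the construct, stood at 1441 ± 696 CPM in the YAP line and 730 ± 332 CPM in the YAPS94A line with shGFP. The log2 difference of 0.98 ± 0.36 did not pass the test (adjusted p = 0.195) and passed it with the replicate number as a block (adjusted p = 0.00563). YAP was above YAPS94A in each replicate pair, at 2099 and 1028, 1511 and 789, and 713 and 372 CPM. With hairpin 1 the log2 fold change of YAP1 was −0.84 ± 0.36 in the YAP line and −0.72 ± 0.36 in the YAPS94A line (adjusted p = 0.253 and 0.206, and with the block 0.0211 and 0.021). With hairpin 2 it was −0.29 ± 0.36 and −0.28 ± 0.36 (adjusted p = 0.692 and 0.732, and with the block 0.639 and 0.614), and in replicate 3 YAP1 stood higher with hairpin 2 than with shGFP, at 1155 and 713 CPM with YAP and 543 and 372 CPM with YAPS94A. ANKRD11, which encodes ANCO1, did not pass in any of these contrasts, except with hairpin 1 in the YAPS94A line under the block (−0.24 ± 0.12 without the block, adjusted p = 0.039 with it).

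**Figure D1:**
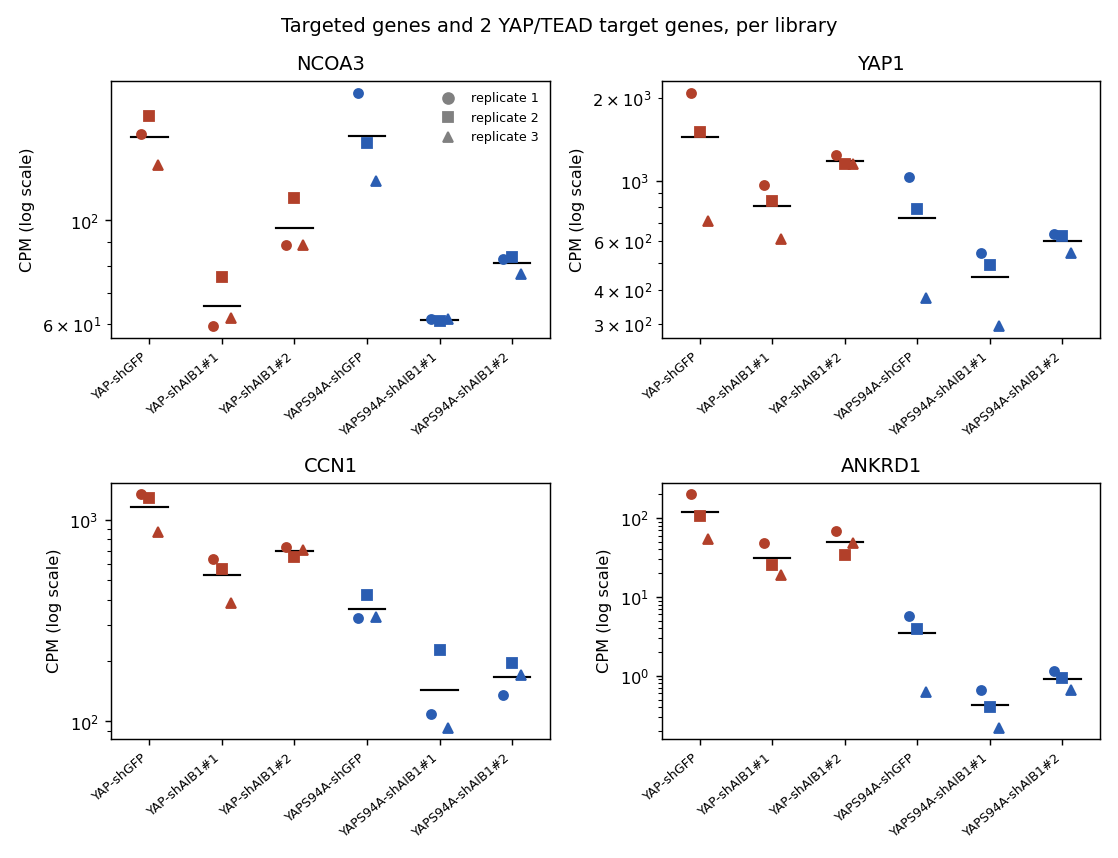
CPM of NCOA3, YAP1, CCN1 and ANKRD1 on a log axis in each of the 6 lines; each point is a library, marked by replicate number, and each bar is the mean of 3 libraries. NCOA3 lies between 59.4 and 112 CPM in the AIB1 hairpin libraries and between 122 and 188 CPM in the shGFP libraries.

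The first comparison asked which genes differed between YAP and its TEAD-binding-deficient form in shGFP cells. The direct YAP/TEAD targets ANKRD1 (chromosome 10, 90912096 to 90921087, minus strand) and CCN1 (chromosome 1, 85580761 to 85584589, plus strand) were higher with YAP. ANKRD1 stood at 120 ± 73.6 CPM with YAP and 3.46 ± 2.61 CPM with YAPS94A, a log2 fold change of 5.11 ± 0.62 (adjusted p = 0.000311), and CCN1 at 1160 ± 253 and 359 ± 55.0 CPM (1.69 ± 0.29, adjusted p = 0.00413). Large differences also lay in COL4A4 and COL4A3, neighbouring basement-membrane collagen genes on chromosome 2 transcribed away from each other, at 3.71 ± 0.32 and 3.42 ± 0.45 (adjusted p = 1.35e-05 and 0.000676). In the other direction CXCL1 and CXCL3, neutrophil-attracting chemokines, stood at −2.20 ± 0.28 and −2.51 ± 0.32 (both adjusted p = 0.000528). IL1B, an inflammatory cytokine, held 16.6 ± 20.3 CPM with YAP and 165 ± 32.8 CPM with YAPS94A (−3.31 ± 0.67, adjusted p = 0.0119).

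In this comparison 258 genes were higher and 221 lower with YAP, 479 in all, of which 266 differed by at least 1 on the log2 scale (124 higher, 142 lower). HSD3B1, a steroid dehydrogenase, had 1868 reads over the 3 YAP libraries and 2 over the 3 YAPS94A libraries, a ratio of 939 after correction for depth (95% exact interval 260 to 7760, counting error only). Further genes higher with YAP were STXBP6, a SNARE regulator (6.10 ± 0.51, adjusted p = 1.11e-05), and THBS1, a matricellular glycoprotein (1.54 ± 0.20, adjusted p = 0.000533). Genes lower with YAP included the antimicrobial S100A7 (−3.10 ± 0.50, adjusted p = 0.00291), the adhesion molecule CEACAM6 (−3.25 ± 0.54, adjusted p = 0.00327) and the Notch ligand JAG1 (−1.27 ± 0.19, adjusted p = 0.00173). With the replicate block 1783 genes were called (836 higher, 947 lower), and in the libraries of description code 061218 alone 562. Over all tested genes the differences in the 2 codes correlated at r = 0.533 (genes are not independent replicates). The count was 200 and 132 without YAP-shGFP replicates 1 and 2, and 268 and 219 without YAPS94A-shGFP replicates 1 and 2. A fit on only these 6 libraries called 45. The IL1B call ended without YAP-shGFP replicate 1 or 2 (adjusted p = 0.0509 and 0.0653).

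Of the 22 measured YAP/TEAD targets, 5 were higher with YAP and none was lower, with 10 higher adjusted over the list alone. The 5 were ANKRD1, CCN1, IGFBP3, an IGF-binding protein (2.18 ± 0.41, adjusted p = 0.008), CRIM1, a BMP antagonist (1.07 ± 0.16, adjusted p = 0.00164), and ARHGEF17, a guanine nucleotide exchange factor (0.75 ± 0.17, adjusted p = 0.0236). The list's median log2 fold change was 0.54 (camera adjusted p = 3.67e-10; adjusted p = 0.0622 with an estimated correlation, 0.0165 with that correlation and the block), and 11 members were higher and 1 lower with the block. CCN2, a further target, had 1.17 ± 0.39 (adjusted p = 0.136, with the block 0.0183), and AMOTL2 0.84 ± 0.24 (adjusted p = 0.0746, with the block 0.000203). The ARHGEF17 call ended without YAP-shGFP replicate 1 or 2 or any 1 of the 3 YAPS94A-shGFP libraries (adjusted p from 0.0509 to 0.149). Of 31 Hippo pathway components 4 were higher and 1 lower (7 and 4 adjusted over the list alone, 10 and 4 with the block). These included TEAD1, a DNA-binding partner of YAP, at 0.73 ± 0.11 (adjusted p = 0.00185), and the upstream tumour suppressors NF2 and WWC1 at 0.60 ± 0.10 and 0.73 ± 0.12 (adjusted p = 0.00297 and 0.00291). The Hippo list had a median of 0.06 (camera adjusted p = 0.0228; adjusted p = 0.406 with an estimated correlation).

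Lineage markers of the mammary epithelium differed between the constructs. Of 11 luminal genes 4 were higher with YAP and none lower (4 and 1 adjusted over the list alone), among them GATA3, the luminal transcription factor (1.83 ± 0.28, adjusted p = 0.00185), and the simple-epithelial keratins KRT8 (1.43 ± 0.26, adjusted p = 0.00574) and KRT18 (1.19 ± 0.15, adjusted p = 0.000311). The luminal list had a median of 0.12 (camera adjusted p = 0.000232; adjusted p = 0.406 with an estimated correlation). Of 18 basal and hemidesmosome genes none was higher and 4 were lower (6 adjusted over the list alone), including TP63, the basal-identity transcription factor (−1.57 ± 0.27, adjusted p = 0.00451). The basal list had a median of −0.37 (camera adjusted p = 1.24e-05; adjusted p = 0.169 with an estimated correlation). The basal keratins KRT5 and KRT14 were not called. Of 32 squamous differentiation genes 1 was higher and 5 lower (1 and 6 adjusted over the list alone; 2 and 14 with the block), with a median of −0.95 (camera adjusted p = 0.00574; adjusted p = 0.735 with an estimated correlation). KRT8 and KRT18 overlap at their ends on opposite strands, so part of their reads cannot be told apart without strand.

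Of 25 NF-kB and inflammatory cytokine genes none was higher with YAP and 9 were lower (1 and 10 adjusted over the list alone), with a median of −0.52 (camera adjusted p = 3.31e-10; adjusted p = 0.108 with an estimated correlation). Of 26 EGF family and MAPK feedback genes 2 were higher and 4 lower (the same counts adjusted over the list alone), among them EREG, an EGF receptor ligand (−1.76 ± 0.20, adjusted p = 0.000211). That list had a median of −0.14 (camera adjusted p = 0.0228; adjusted p = 0.108 with an estimated correlation). Of 5 measured fibroblast genes none was higher and 1, the proteoglycan gene DCN, was lower (−2.60 ± 0.48, adjusted p = 0.00731; 3 lower adjusted over the list alone and 3 with the block). DCN lost its call without YAP-shGFP replicate 2 (adjusted p = 0.064). The fibroblast list had a median of −1.55 (camera adjusted p = 0.00152; adjusted p = 0.108 with an estimated correlation). The other lists past the test moved by little per gene: cholesterol biosynthesis (median 0.25, camera adjusted p = 0.000225), ribosomal protein (0.21, 2.48e-07), p53 target (0.12, 0.011), S phase and E2F (0.17, 0.0444) and actin and SRF target genes (0.20, 0.0444). Between them these 5 had 1 called member, the actin-binding LIMA1 (−0.52 ± 0.12, adjusted p = 0.0198), whose call ended without replicate 1 or 2 of YAP-shGFP or of YAPS94A-shGFP (adjusted p from 0.0708 to 0.157). Adjusted over the list alone, 4 p53 targets were higher, and 1 actin gene was higher and 1 lower. With the block 5 cholesterol, 8 ribosomal protein, 4 p53 target, 1 S phase and 5 actin genes were higher, and 1 actin gene was lower. With an estimated correlation their adjusted p was 0.51, 0.606, 0.51, 0.808 and 0.51.

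The other 16 lists did not pass. Mesenchymal genes had 1 higher and 2 lower of 21 (7 and 4 adjusted over the list alone, 9 and 6 with the block), with a positive median (0.29) and a negative mean (−0.07). Extracellular matrix genes had 6 higher and 2 lower of 34 (9 and 9 adjusted over the list alone, 12 and 10 with the block), with a median of −0.02, a mean of −0.22 and an upward rank in the test. Glycolysis and hypoxia genes had 3 higher of 27, Wnt pathway genes 2 higher and 1 lower of 19, and epithelial junction genes 2 higher of 26, the same counts as adjusted over the list alone; with the block epithelial junction genes had 2 higher and 3 lower. The Wnt list had a negative median and mean (−0.07 and −0.12) and an upward rank in the test. TGF-beta targets had 1 higher and 1 lower of 18, and Notch genes 1 lower of 17 (1 and 2, and 0 and 2, adjusted over the list alone; 2 and 3, and 1 and 4, with the block). The G2/M list (median 0.15, camera adjusted p = 0.142) passed with the block at the preset correlation (adjusted p = 0.00511). Without the block it did not pass with an estimated correlation. The p160 coactivator, interferon, unfolded protein response, mitochondrially encoded, histone, immediate early stress, endothelial and leukocyte lists had no called member; adjusted over the list alone, 1 histone and 1 leukocyte gene were lower. With the block 1 p160 coactivator gene was higher and 1 lower, 1 stress response gene was higher, and 1 interferon, 1 histone and 1 leukocyte gene were lower. Of the 13 lists past the test, none held with an estimated correlation.

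The construct comparison was repeated in cells with hairpin 1 and hairpin 2, which share no library with the shGFP comparison. ANKRD1 was higher with YAP in both, by 6.15 ± 0.75 and 5.75 ± 0.70 (adjusted p = 0.000188 and 0.000243), as was CCN1, by 1.89 ± 0.29 and 2.07 ± 0.29 (adjusted p = 0.00113 and 0.000662). COL4A4 stood at 4.09 ± 0.33 and 3.83 ± 0.33, and TP63 at −1.92 ± 0.27 and −2.20 ± 0.28. Under hairpin 1, 350 genes were higher and 256 lower; under hairpin 2, 319 and 222. Genes called in all 3 arms numbered 134 higher and 99 lower (396 and 327 with the block). Of the 479 shGFP calls 460 had the same sign in both hairpin arms. With the block the 2 arms called 1888 (876 higher, 1012 lower) and 1863 (968 higher, 895 lower). In the 061218 libraries alone they called 603 and 445. Under hairpin 1 the count was 343 and 349 without YAP-shAIB1#1 replicates 1 and 2, and 363 and 391 without YAPS94A-shAIB1#1 replicates 2 and 3. Under hairpin 2 it was 346 and 352 without YAP-shAIB1#2 replicates 1 and 2, and 322 without YAPS94A-shAIB1#2 replicate 2.

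The next comparison asked what lowering AIB1 changed in the YAP line, counting genes called with both hairpins in 1 direction. AREG, an EGF receptor ligand, stood at 1036 ± 44.9 CPM with shGFP, 470 ± 68.4 with hairpin 1 and 288 ± 21 with hairpin 2, and fell by 1.14 and 1.85 on the log2 scale (adjusted p = 0.000112 and 1.06e-06). Its relative EREG fell by 2.01 and 1.10 (adjusted p = 6.36e-05 and 0.00396). SAMSN1, an adaptor of immune signalling, had −2.92 ± 0.30 and −3.48 ± 0.31 (adjusted p = 4.99e-05 and 1.13e-05), and STC2, a secreted glycoprotein hormone, −1.41 ± 0.21 and −1.20 ± 0.21 (adjusted p = 0.000975 and 0.00245). PLAAT4, a retinoid-inducible phospholipase, rose by 2.21 ± 0.31 and 3.32 ± 0.31 (adjusted p = 0.000522 and 1.39e-05), and APOL3, an interferon-inducible apolipoprotein L, by 1.79 ± 0.16 and 2.28 ± 0.16 (adjusted p = 1.55e-05 and 8.43e-07). SOAT1, which esterifies cholesterol, rose by 1.74 ± 0.18 and 1.89 ± 0.18, and E2F2, a cell-cycle transcription factor, by 1.79 ± 0.25 and 1.17 ± 0.25.

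With both hairpins 142 genes rose and 47 fell in the YAP line. Hairpin 1 alone called 272 higher and 268 lower, and hairpin 2 alone 806 and 506; 18 genes were called in opposite directions. Independent lists of these sizes would share 14.7 higher and 9.06 lower genes. Simulated unchanged groups shared 0. Hardly any gene is called where none changes, so this 0 says little about the shared controls. The fold changes of the hairpins correlated across genes at r = 0.397 (0.499 simulated), with a covariance of 0.115 against 0.0584 simulated. The 3 shGFP libraries cannot be split, so part of the excess over independent lists may come from the shared controls. With the block the count was 839 (560 higher, 279 lower), and single hairpins called 2365 and 3970. In the 061218 libraries alone the count was 176. Without YAP-shGFP replicate 1 or 2 it was 97 or 103, and without YAP-shAIB1#1 replicate 1, 2 or 3 it was 112, 102 or 124.

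Among fixed lists in the YAP line, cholesterol biosynthesis genes had 3 higher and none lower of 23 (the same counts adjusted over the list alone, 6 higher with the block), with a median of 0.23 (camera adjusted p = 4.76e-05; adjusted p = 0.771 with an estimated correlation). MSMO1, a sterol demethylase, rose by 0.84 ± 0.16 and 0.82 ± 0.16 (adjusted p = 0.00514 and 0.0043), and INSIG1, which retains the sterol sensor SCAP, by 1.41 ± 0.20 and 0.90 ± 0.20 (adjusted p = 0.000722 and 0.0117). The INSIG1 call with hairpin 2 ended without YAP-shGFP replicate 2 (adjusted p = 0.0648). Of 25 NF-kB genes 1 was higher and 3 were lower (1 and 4 adjusted over the list alone, 1 and 6 with the block), with a median of −0.27 (camera adjusted p = 0.000873; adjusted p = 0.771 with an estimated correlation). CXCL3 was among the lower ones at −1.83 ± 0.35 and −1.91 ± 0.35 (adjusted p = 0.00594 and 0.00335). Of 26 EGF family genes 2, AREG and EREG, were lower (the same count adjusted over the list alone), with a median of −0.15 (camera adjusted p = 0.00142; adjusted p = 0.0427 with an estimated correlation, and 0.238 with that correlation and the block). This was the 1 list of 5 past the test in this line that held with an estimated correlation.

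Of 25 unfolded protein and integrated stress response genes 1 was lower (3 adjusted over the list alone, 5 with the block), CHAC1, a glutathione-degrading enzyme, at −2.30 ± 0.44 and −1.97 ± 0.44 (adjusted p = 0.00667 and 0.0112). The hairpin 2 call ended without YAP-shGFP replicate 2 or YAP-shAIB1#2 replicate 2 (adjusted p = 0.0501 and 0.0556). The list had a median of −0.23 (camera adjusted p = 4.99e-05; adjusted p = 0.0508 with an estimated correlation). The 28 interferon-response genes had a median of 0.56 (camera adjusted p = 0.00022; adjusted p = 0.771 with an estimated correlation) with no called member, also adjusted over the list alone, and 7 higher with the block. YAP/TEAD targets had no called member, also adjusted over the list alone, with 3 lower under the block. Their median was −0.15 (camera adjusted p = 0.0665, with the block 0.0193 at the preset correlation). Without the block the list did not pass with an estimated correlation. With hairpin 1 by itself 1 target was higher and 4 were lower (1 and 8 adjusted over the list alone, 1 and 8 with the block), with a median of −0.21 (camera adjusted p = 0.000955; adjusted p = 0.352 with an estimated correlation). With hairpin 2 by itself 1 was higher and none lower (none adjusted over the list alone, 2 and 5 with the block), with a median of −0.07 (camera adjusted p = 0.744). Between the hairpins the targets were higher with hairpin 2 (3 called, 4 adjusted over the list alone; 10 higher and 4 lower with the block; median 0.37, camera adjusted p = 0.0283; adjusted p = 0.626 with an estimated correlation). CCN1 had −1.12 ± 0.28 with hairpin 1 (adjusted p = 0.0374) and −0.73 ± 0.28 with hairpin 2 (adjusted p = 0.122, with the block 0.0219). The hairpin 1 call ended without YAP-shGFP replicate 1 or 2 or any 1 of the 3 YAP-shAIB1#1 libraries (adjusted p from 0.0564 to 0.161). ANKRD1 had −1.95 ± 0.52 and −1.26 ± 0.51 (adjusted p = 0.0516 and 0.143, with the block 7.27e-05 and 0.00314). Mesenchymal (camera adjusted p = 0.172), epithelial junction (0.103) and G2/M genes (0.0771) passed with the block at the preset correlation (adjusted p = 0.0424, 0.00819 and 0.00042). Without the block none of these lists passed with an estimated correlation. The cholesterol, NF-kB and EGF family lists also passed with hairpin 1 by itself (camera adjusted p = 3.74e-08, 2.93e-06 and 0.000192; 0.352, 0.352 and 0.0165 with an estimated correlation, and 0.104 for the last with that correlation and the block) and not with hairpin 2 (0.096, 0.496 and 0.168). The test between the hairpins gave 0.0266, 0.0155 and 0.185 for them (0.705, 0.705 and 0.5 with an estimated correlation). Extracellular matrix genes had a median of −0.12 with hairpin 1 and 0.27 with hairpin 2 (camera adjusted p = 0.0177 and 0.02; 0.393 and 0.506 with an estimated correlation), and their mean effect did not pass (0.708).

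In the YAPS94A line, lowering AIB1 was accompanied by lower expression of mesenchymal genes with both hairpins. FN1, the matrix protein fibronectin, went from 2661 ± 1220 CPM to 271 ± 96.8 with hairpin 1 and 536 ± 211 with hairpin 2, at −3.30 ± 0.42 and −2.31 ± 0.40 (adjusted p = 0.000158 and 0.00212). CDH2, the mesenchymal cadherin, had −2.08 ± 0.18 and −1.15 ± 0.18 (adjusted p = 8.29e-06 and 0.000889), TGFBI, a TGF-beta-induced matrix protein, −1.97 ± 0.25 and −1.34 ± 0.25 (adjusted p = 0.000173 and 0.0036), and POSTN, the matricellular protein periostin, −4.07 ± 0.45 and −4.49 ± 0.46 (adjusted p = 4.66e-05 and 3.61e-05). Of 21 measured mesenchymal genes 7 fell and none rose (10 fell adjusted over the list alone, 11 with the block). The list had a median of −1.20 (camera adjusted p = 6.33e-14; adjusted p = 0.00412 with an estimated correlation). ZEB2, a transcriptional repressor of E-cadherin, had −2.76 ± 0.73 and −2.85 ± 0.75; its calls ended without YAPS94A-shGFP replicate 2 or 3, YAPS94A-shAIB1#1 replicate 1 or 2, or YAPS94A-shAIB1#2 replicate 1 or 2 (adjusted p from 0.05 to 0.113). VIM, the intermediate filament vimentin, had −2.24 ± 0.69 and −1.92 ± 0.68 (adjusted p = 0.0405 and 0.102, with the block 1.72e-05 for hairpin 2). The hairpin 1 call of VIM ended without YAPS94A-shGFP replicate 2 or 3 or any 1 of the 3 YAPS94A-shAIB1#1 libraries (adjusted p from 0.05 to 0.148).

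**Figure D2:**
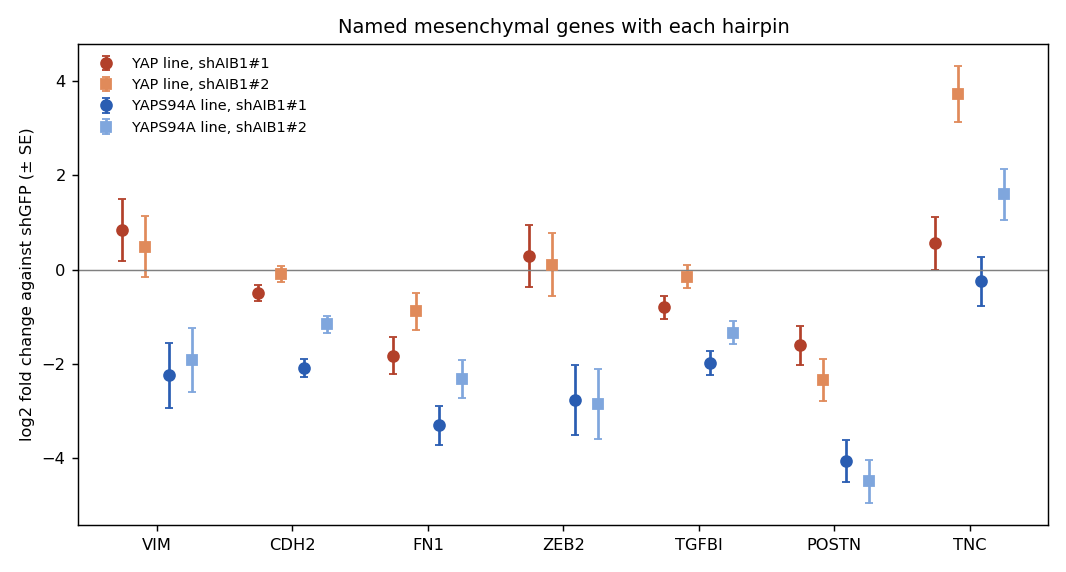
Log2 fold change ± standard error of 7 mesenchymal and matrix genes with each AIB1 hairpin against shGFP, in the YAP and the YAPS94A line. FN1, CDH2, TGFBI and POSTN lie below 0 with both hairpins in the YAPS94A line, between −1.15 and −4.49.

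AREG and EREG fell here too, AREG by 1.87 and 1.90 and EREG by 2.08 and 0.99 on the log2 scale. The chemokines CXCL3 and CCL20 had −3.10 ± 0.33 and −3.24 ± 0.34, and −2.59 ± 0.32 and −2.19 ± 0.32. PLAAT4 rose by 3.69 ± 0.34 and 4.24 ± 0.34 and APOL3 by 2.82 ± 0.17 and 2.99 ± 0.17, and the retinoid-responsive genes RARRES1 and CRABP2 by 3.18 ± 0.55 and 3.13 ± 0.55, and 2.72 ± 0.56 and 3.89 ± 0.58. With both hairpins 395 genes rose and 228 fell, 623 in all. Hairpin 1 alone called 1087 higher and 996 lower, and hairpin 2 alone 763 and 489; 17 went in opposite directions. Independent lists would share 55.4 higher and 32.6 lower genes. Simulated unchanged groups shared 0, which again says little about the shared controls. The hairpins correlated across genes at r = 0.626 (0.491 simulated), with a covariance of 0.245 against 0.0575 simulated; here too part of the excess may come from the 3 shared controls, which cannot be split. With the block 1798 genes were called with both hairpins (1102 higher, 696 lower), and 4979 and 3396 with single hairpins. In the 061218 libraries alone 682 were called. Without YAPS94A-shGFP replicate 2 the count was 260, without YAPS94A-shAIB1#1 replicate 2 or 3 it was 400 or 414, and without YAPS94A-shAIB1#2 replicate 2 it was 349.

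Cholesterol biosynthesis genes rose in the YAPS94A line, 3 of 23 (6 adjusted over the list alone, 11 with the block), with a median of 0.57 (camera adjusted p = 3.48e-10; adjusted p = 0.186 with an estimated correlation). HMGCS1, a synthase early in the pathway, rose by 1.39 ± 0.22 and 1.05 ± 0.22, and MSMO1 by 1.13 ± 0.16 and 0.91 ± 0.16. Of 28 interferon-response genes 3 rose, among them BST2 and OAS1 (4 adjusted over the list alone, 14 with the block), with a median of 0.72 (camera adjusted p = 7.88e-06; adjusted p = 0.482 with an estimated correlation). BST2, the antiviral tetherin, stood at 0.463 ± 0.260 CPM with shGFP and at 4.11 ± 2.01 and 4.31 ± 2.24 CPM with the hairpins. Without YAPS94A-shGFP replicate 2 neither BST2 nor OAS1 was called with either hairpin (adjusted p from 0.0663 to 0.156). Leaving out YAPS94A-shGFP replicate 3, or replicate 1 or 2 of YAPS94A-shAIB1#1 or YAPS94A-shAIB1#2, also ended at least 1 of their calls (adjusted p from 0.064 to 0.171).

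Of 11 luminal genes 2 rose, KRT8 and KRT18, the latter by 0.72 ± 0.14 and 0.70 ± 0.14 (2 rose and 1 fell adjusted over the list alone, 6 and 1 with the block), with a median of 0.79 (camera adjusted p = 0.00429; adjusted p = 0.382 with an estimated correlation). KRT8 had 1.00 ± 0.25 and 0.87 ± 0.25; its calls ended without YAPS94A-shGFP replicate 2 or 3, YAPS94A-shAIB1#1 replicate 3 or any 1 of the 3 YAPS94A-shAIB1#2 libraries (adjusted p from 0.0556 to 0.154). YAP/TEAD targets had 2 lower of 22 (the same count adjusted over the list alone, 7 with the block) and a median of −0.32 (camera adjusted p = 2.12e-05; adjusted p = 0.118 with an estimated correlation). The lower ones were CCN1, at −1.33 ± 0.29 and −1.11 ± 0.28 (adjusted p = 0.00636 and 0.0237), and IGFBP3, at −2.83 ± 0.43 and −1.49 ± 0.41 (adjusted p = 0.000646 and 0.0335). With hairpin 2 the CCN1 call ended without YAPS94A-shGFP replicate 2 or YAPS94A-shAIB1#2 replicate 1 or 3 (adjusted p = 0.104, 0.0965 and 0.0527). That of IGFBP3 ended without YAPS94A-shGFP replicate 1 or 2 or any 1 of the 3 YAPS94A-shAIB1#2 libraries (adjusted p from 0.0623 to 0.142).

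Extracellular matrix genes had 1 higher and 6 lower of 34 (3 and 8 adjusted over the list alone, 4 and 9 with the block; median −0.33, camera adjusted p = 2.12e-05; adjusted p = 0.0651 with an estimated correlation, 0.011 with that correlation and the block). EGF family genes had 3 lower of 26 (the same count adjusted over the list alone, 2 higher and 5 lower with the block; median −0.15, camera adjusted p = 0.000129; adjusted p = 0.00851 with an estimated correlation). NF-kB genes had 1 higher and 5 lower of 25 (2 and 7 adjusted over the list alone, 2 and 9 with the block; median −0.90, camera adjusted p = 9.94e-06; adjusted p = 0.279 with an estimated correlation). Stress response genes had 2 lower of 25 (the same count adjusted over the list alone, 5 with the block; median −0.29, camera adjusted p = 0.000129; adjusted p = 0.0651 with an estimated correlation). Basal genes had 2 lower of 18 (8 adjusted over the list alone, 1 higher and 8 lower with the block; median −0.33, camera adjusted p = 0.000796; adjusted p = 0.301 with an estimated correlation). Also past the test were epithelial junction (median 0.24, camera adjusted p = 0.0238), G2/M (0.32, 0.013), S phase (0.28, 0.0022), actin (−0.15, 0.017) and ribosomal protein genes (0.25, 2.91e-06), with 2, 0, 1, 0 and 0 higher and 0, 0, 0, 2 and 0 lower. Adjusted over the list alone they had the same counts, except for 4 actin genes lower, and with the block 9, 5, 4, 0 and 0 higher and 0, 0, 0, 9 and 0 lower. With an estimated correlation their adjusted p was 0.752, 0.786, 0.718, 0.334 and 0.562, and of 15 lists only the mesenchymal and EGF family ones held. The squamous, p53 and TGF-beta lists (camera adjusted p = 0.123, 0.0876 and 0.0744) passed with the block at the preset correlation (adjusted p = 0.002, 0.0318 and 0.031). Without the block none of these lists passed with an estimated correlation. Of 5 fibroblast genes 1 rose and 3 fell (the same counts adjusted over the list alone): FBLN1, a fibulin of the extracellular matrix, rose by 2.63 ± 0.26 and 2.69 ± 0.26, and DCN had −3.75 ± 0.52 and −2.59 ± 0.48. That list did not pass (median −2.16, camera adjusted p = 0.0876). Among the lists past the test here, the extracellular matrix, EGF family, S phase, G2/M, actin and ribosomal protein lists passed with hairpin 1 by itself (camera adjusted p = 7.34e-09, 1.23e-05, 0.00032, 0.00649, 0.0072 and 1.82e-20) and not with hairpin 2 (0.249, 0.0618, 0.0904, 0.132, 0.153 and 0.308; with the block 0.0359 for S phase and 0.00739 for G2/M). With an estimated correlation the extracellular matrix and EGF family lists held with hairpin 1 (adjusted p = 0.0111 and 0.00569), and the other 4 had adjusted p from 0.2 to 0.781. The epithelial junction list passed with hairpin 2 by itself and not with hairpin 1 (0.0267 and 0.115; 0.846 and 0.799 with an estimated correlation; with the block 0.0362 for hairpin 1). Between the hairpins these 7 lists had camera adjusted p of 3.09e-07, 0.00744, 0.0478, 0.164, 0.159, 1.16e-33 and 0.632, and none held with an estimated correlation (adjusted p from 0.0529 to 0.937; 0.00736 for extracellular matrix genes with that correlation and the block).

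**Figure D3:**
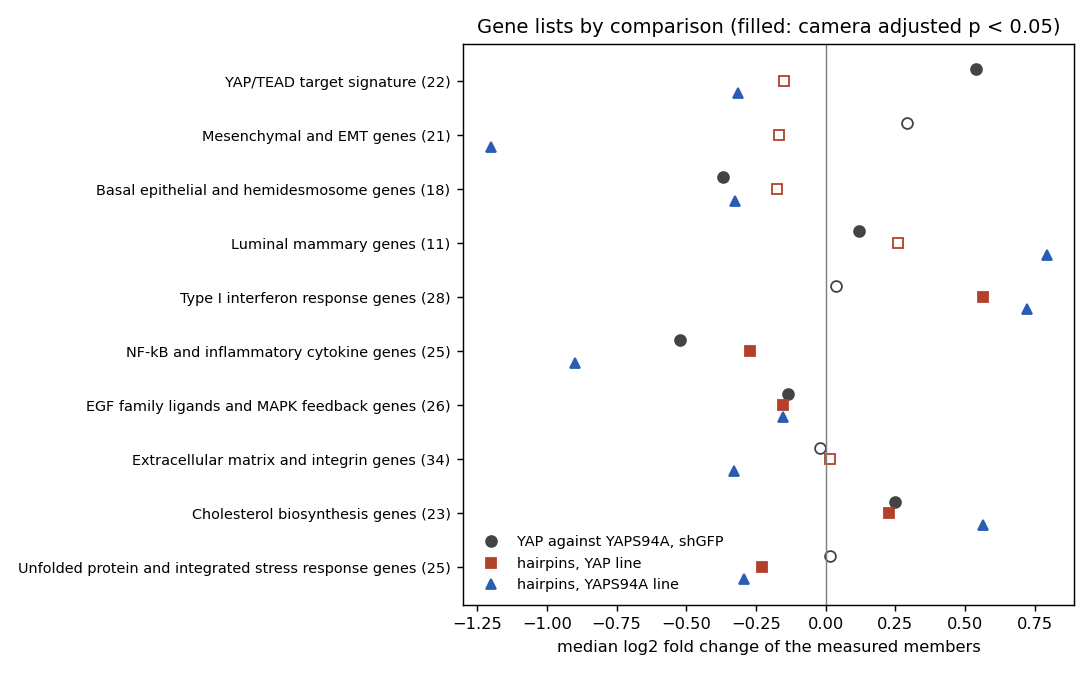
Median log2 fold change of 10 fixed gene lists for YAP against YAPS94A with shGFP and for the mean of the AIB1 hairpins in each line; filled points passed camera with the preset correlation and the number of measured genes stands in parentheses. The mesenchymal list lies at 0.29, −0.17 and −1.20.

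Whether the effect of the hairpins differed between the lines was tested as an interaction, the mean hairpin effect with YAP minus that with YAPS94A. Mesenchymal genes stood apart: their median difference was 0.96 (camera adjusted p = 6.66e-20; adjusted p = 0.00108 with an estimated correlation), and 10 of 21 members were higher adjusted over the list alone. Extracellular matrix genes had a median of 0.35 (camera adjusted p = 2.74e-11; adjusted p = 0.00675 with an estimated correlation), with 2 of 34 higher adjusted over the list alone. Over all genes no member of either list was called, and with the block 8 and 4 were higher. These were the 2 lists of 14 past the test that held with an estimated correlation. The G2/M, NF-kB and mitochondrially encoded lists had medians of −0.07, 0.23 and −0.21 (camera adjusted p = 0.307, 0.0638 and 0.123). They passed with the block at the preset correlation (adjusted p = 0.0387, 0.0186 and 0.00111). Without the block none of these lists passed with an estimated correlation. VIM had an interaction of 2.74 ± 0.82 and FN1 of 1.45 ± 0.47 (adjusted p = 0.68 and 0.819, with the block 0.000543 and 0.0156). No single gene passed in edgeR, with 685 at an unadjusted p under 0.05; DESeq2 called 20, limma-voom 0, and the replicate block 96 (77 higher, 19 lower). Taken per hairpin the counts were 0 and 0, and 92 and 11 with the block. In simulated data without the pairing this contrast called 6.2% of genes changed by 1.5-fold, 32.8% at 2-fold and 68.8% at 4-fold. The 1 gene called without YAP-shGFP replicate 3 and the 2 without YAP-shAIB1#2 replicate 2 were the only calls when single libraries were left out.

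Across genes the mean hairpin effects of the lines, which share no library, correlated at r = 0.683 (Spearman 0.636; genes are not independent replicates), against −0.002 in simulated unchanged groups, with a covariance of 0.175 (−0.0001 simulated). Of the 189 genes called in the YAP line 186 had the same sign with both hairpins in the YAPS94A line, and of the 623 called there 580 had the same sign in the YAP line. Both lines called 107 genes higher and 34 lower, against 3.75 and 0.72 for independent lists. Among the 623 genes, which were chosen in the YAPS94A line, the median absolute log2 fold change was 0.61 in the YAP line and 1.01 in the YAPS94A line. Among the 189 genes chosen in the YAP line it was 0.83 there and 0.85 in the YAPS94A line.

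The hairpins were also compared with each other. In the YAP line all 45 ribosomal protein genes, components of the translation machinery, were lower with hairpin 2 than with hairpin 1 (median −0.72, camera adjusted p = 1.05e-43; adjusted p = 0.192 with an estimated correlation). In the YAPS94A line 32 of 45 were lower (45 adjusted over the list alone and with the block; median −0.59, camera adjusted p = 1.16e-33; adjusted p = 0.247 with an estimated correlation). The share of gene reads in mitochondrially encoded genes was higher with hairpin 2 than with hairpin 1 in 6 of 6 replicate pairs, at 3.47% to 9.25% against 1.49% to 5.85% with YAP, and 5.19% to 9.25% against 2.38% to 6.37% with YAPS94A. That list had a median of 0.78 and 0.57 in the lines (camera adjusted p = 0.0232 and 0.0385; adjusted p = 0.705 and 0.768 with an estimated correlation), with none of its 13 members called and 10 and 8 higher with the block. Further lists passed only with the block, at the preset correlation. In the YAP line these were the basal (camera adjusted p = 0.0745, with the block 0.0319), epithelial junction (0.133 and 0.031) and interferon lists (0.0865 and 0.00797). In the YAPS94A line these were the basal (0.0709 and 0.0276) and G2/M lists (0.164 and 0.017). NCOA3 itself was higher with hairpin 2 by 0.55 ± 0.15 in the YAP line (adjusted p = 0.0249) and by 0.40 ± 0.15 in the YAPS94A line (adjusted p = 0.118, with the block 0.022). Hairpin 2 against hairpin 1 gave 967 higher and 834 lower genes in the YAP line and 580 and 513 in the YAPS94A line. Of the 1801 YAP-line calls 1792 had the same sign in the YAPS94A line and 882 were called in both. With the block 4840 and 3714 genes were called, and in the 061218 libraries alone 1810 and 895. The YAP-line count was 1046, 915 and 916 without YAP-shAIB1#1 replicates 1, 2 and 3, and 880 and 958 without YAP-shAIB1#2 replicates 1 and 2. The YAPS94A-line count was 521 and 424 without YAPS94A-shAIB1#1 replicates 2 and 3, and 476 and 663 without YAPS94A-shAIB1#2 replicates 1 and 2.

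Last, genes called in the construct comparison were set against those called with both hairpins in the YAP line. The exact tests here take genes as independent draws, which genes that move together are not. Lower in both were 5 genes, CXCL3, POSTN, EREG, CCL20 and PNLIPRP3 (0.69 for independent lists; two-sided Fisher's exact p = 0.000622, adjusted 0.00299 over the 24 tests of this family). Higher in both were 8 genes, among them APOL3 (2.45 for independent lists; exact p = 0.00323, adjusted 0.0129). Higher with YAP and lower with the hairpins were COL12A1 and MYL7, and the reverse held for TSC22D1 (0.81 and 2.10 for independent lists, exact p = 0.194 and 0.727). With the construct comparison under hairpins 1 and 2 instead, 6 and 6 genes were higher in both (3.32 and 3.03 for independent lists). This no longer passed (adjusted exact p = 0.2 and 0.195). Lower in both were 4 and 4 genes (adjusted exact p = 0.0201 and 0.0153). Higher with YAP and lower with the hairpins were 5 and 4 (1.1 and 1 for independent lists, adjusted exact p = 0.0153 and 0.0376). Some calls of the genes named here ended when a single library was left out of the fit without the block. POSTN lost its construct call without YAP-shGFP replicate 2 (adjusted p = 0.0674), and its hairpin 1 call without YAP-shGFP replicate 1 or 3 or any 1 of the 3 YAP-shAIB1#1 libraries (adjusted p from 0.0918 to 0.199). CCL20 lost its hairpin 1 call without YAP-shGFP replicate 1 or any 1 of the 3 YAP-shAIB1#1 libraries (adjusted p from 0.0584 to 0.0847). COL12A1 lost hairpin calls without YAP-shGFP replicate 2, YAP-shAIB1#1 replicate 1 or 3, or YAP-shAIB1#2 replicate 1 or 2 (adjusted p from 0.0709 to 0.136). PNLIPRP3, MYL7 and TSC22D1 lie outside the rule for named genes and were chosen after their values were seen. Across genes the effects correlated at r = −0.102 (−0.578 in simulated unchanged groups), with a covariance of −0.0244 against −0.0586, a difference of 0.0341. Simulated groups shared 0 calls, which says little, since hardly any gene is called where none changes. The 3 YAP-shGFP libraries enter the comparisons with opposite signs, so their chance values pull the effects apart and add only to overlaps in opposite directions. Comparisons that share no library used the calls of a single hairpin, so the lists were longer as well. For the construct under hairpin 1 against hairpin 2 the overlap was 129 genes. Of these, 51 were higher with YAP and with the hairpin and 44 lower with YAP and higher with the hairpin (18.9 and 13.8 for independent lists; exact p = 7.43e-11 and 6.13e-12, adjusted 8.92e-10 and 1.47e-10). A further 18 were higher with YAP and lower with the hairpin and 16 lower in both (11.8 and 8.66 for independent lists; adjusted exact p = 0.123 and 0.0386). For the construct under hairpin 2 against hairpin 1 it was 46 genes, of which 22 were higher with YAP and lower with the hairpin (5.71 for independent lists; exact p = 7.01e-08, adjusted 5.61e-07). The other directions held 8 higher in both, 7 lower with YAP and higher with the hairpin, and 9 lower in both (5.80, 4.04 and 3.98 for independent lists; adjusted exact p = 0.468, 0.195 and 0.0376).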

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

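Chosen only after the results were seen were the tests of YAP1 level as the whole cause and at matched level, the 2 fits with the replicate number as a block, the test on COL1A2 and COL3A1, and the count of 15 ribosomal protein genes with the values per line beside it; the others in this part were planned.

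The effect of the AIB1 hairpins differed between the YAP and YAPS94A lines for 14 gene lists, by camera on the interaction. The difference is the hairpin effect with YAP minus that with YAPS94A, so a positive value can be a smaller fall with YAP: mesenchymal medians were −0.17 with YAP and −1.20 with YAPS94A. Positive medians were found for mesenchymal (0.96), extracellular matrix (0.35), YAP/TEAD target (0.18), p160 coactivator (0.13), basal (0.20), TGF-beta target (0.24), actin (0.12) and fibroblast genes (1.99). Their camera adjusted p was 6.66e-20, 2.74e-11, 0.000779, 0.0494, 0.00511, 0.00251, 0.00819 and 0.00202. Negative medians were found for squamous (−0.56), luminal (−0.34), S phase (−0.18), interferon (−0.19), cholesterol (−0.22) and ribosomal protein genes (−0.27), at 0.000755, 0.00346, 0.0202, 0.0494, 0.000207 and 1.03e-16. With an estimated correlation the mesenchymal and extracellular matrix lists held (adjusted p = 0.00108 and 0.00675), and the others had adjusted p from 0.104 to 0.79.

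Single named genes differed between the lines once the replicate number was a block; without it none passed. The blocked interaction was positive for the mesenchymal and matrix genes ZEB2 (3.13), DCN (3.12), VIM (2.80), POSTN (2.35), FN1 (1.42), COL6A1 (1.39), CDH2 (1.32), TGFBI (1.17) and COL12A1 (0.74). It was also positive for the ligand WNT5A (2.27), the receptor kinase ROS1 (1.99), LIMA1 (0.61) and the kinase MAP4K4 (0.50). It was negative for S100A7 (−1.94), S100A8 (−1.71), FBLN1 (−1.32) and S100A9 (−1.05). The real interaction count of genes was 0, which any split reaches by construction, so the 100 of 100 splits that did (highest other 21) say nothing about chance.

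The first pattern weighed is the mesenchymal interaction. Fibroblasts mixed into the YAPS94A-shGFP libraries would bring fibrillar collagen transcripts, yet COL1A2 and COL3A1 reached at most 0.056 CPM there while DCN stood between 39.8 and 112 CPM. The planned test, the collagen sum over DCN, gave 0.306, above its bound of 0.1 and by itself undecided, since COL1A1 is also present in the other lines. No single library carried the difference: the highest adjusted p of the list with an estimated correlation was 0.0274 when 1 library was left out (YAPS94A-shGFP replicate 3); with all libraries and the replicate number as a block it was 0.000855, which is no test of that number, since each occurs once in every line. The construct, which the design names, stays open without a test of its own, as do differences between the derivatives that arose during their selection.

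The next pattern is the higher level of YAP/TEAD targets with YAP, where YAP1 itself was higher by 0.98 ± 0.36. With log2 YAP1 as a covariate the median of the 5 called targets went from 1.69 to 1.28, and 4 of 5 still passed, in a fit that called 2344 genes against 479 and so had an easier threshold; IGFBP3 went from 2.18 to 1.32, and ARHGEF17 ended at 0.43 ± 0.15 (adjusted p = 0.0583), from 0.75 ± 0.17, its estimate being smaller at a like error. The other estimates, 3.83 ± 0.28 for ANKRD1, 1.28 ± 0.30 for CCN1, 1.32 ± 0.29 for IGFBP3 and 0.96 ± 0.18 for CRIM1, lie far from 0 for their errors. However, in both shGFP lines YAP1 fell with the replicate number, from 2099 to 713 CPM with YAP and from 1028 to 372 CPM with YAPS94A. The covariate therefore partly stands for that number, and the fit cannot decide whether YAP1 level is the whole cause. Whether YAP1 level contributes cannot be told apart from the construct, because each construct comes with its own YAP1 level. YAP-shAIB1#1 and YAPS94A-shGFP differ in hairpin too, and in YAP1 by 0.14 ± 0.36. Between them 2 of 5 were higher, ANKRD1 (3.16) and ARHGEF17 (0.75), while CCN1 (0.57), IGFBP3 (0.46) and CRIM1 (−0.21) were not called. With the replicate number as a block 5 of 5 passed, which is no test of that number in this balanced design; the loss of TEAD binding, which the design names, stays open.

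The last pattern is the lower level of 45 ribosomal protein genes with hairpin 2 than with hairpin 1 in the YAP line. Taking out a trend on exon length, summed over all annotated exons of a gene, left 44 called, which argues against a bias on that length. Thinning all libraries to the smallest left 45, which argues against depth, though gene reads differed little before it (14482437 to 21368384). A weaker knockdown by hairpin 2 would make genes go against the hairpin 1 effect of the YAPS94A line. So would an effect particular to hairpin 1 that recurs in both lines, so the signs cannot separate the 2. Of all genes called between the hairpins 80.4% did so, between the bounds set in advance. All 45 of 45 ribosomal protein genes did, with YAPS94A-line medians of 0.53 with hairpin 1 and −0.04 with hairpin 2. A weaker knockdown therefore stays open. In the YAP line their medians were 0.35 and −0.36. Of these genes 15 were called lower with hairpin 2 than with shGFP while their hairpin 1 estimate lay above 0, counted by sign only. A response to remaining NCOA3 in 1 direction would not give that. The count does not decide, since the hairpin 1 side needed no call and these genes move together. An effect particular to 1 hairpin stays open as well. The mitochondrial share was also higher with hairpin 2 in 6 of 6 pairs, and a difference in cell state or RNA quality was not tested.

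Other splits of the same libraries were counted for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split was the 1 with as many calls in each of 5 comparisons: 479 genes for the construct with shGFP (highest other 0), 606 and 541 under hairpins 1 and 2 (highest other 0 and 0), and 1801 and 1093 between the hairpins in the YAP and YAPS94A lines (highest other 0 and 1). For genes called with both hairpins, 2 of 100 splits reached the 189 of the YAP line and 1 of 100 the 623 of the YAPS94A line, with highest others of 423 and 416. Most of these splits break the pairing of the replicates, so chance is not excluded on this basis. The split with 423 calls set the 3 YAP-shAIB1#2 libraries as control, which points to the structure of the samples: by itself that group differed from the others in many genes. The split with 416 calls kept the 3 YAPS94A-shGFP libraries as control and only mixed the hairpins. Among the 12 other splits that part as many replicate pairs, too few for a share under 0.05, the highest counts were 134 and 352. Each of these set the 3 shAIB1#1 libraries of its line as control, so neither is a random mix of the libraries. In the YAP line the 189 lay between the 134 and 423 of splits with the libraries of 1 AIB1 hairpin as shared control. A count of that size is therefore not particular to shGFP as control. In the YAPS94A line the 623 lay above the 352 and 78 of such splits.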

How the results depend on the processing

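The 061218 libraries alone and the overlaps without a shared library were added after the data were seen; other alternatives were planned. No called value reversed, but the balance of construct calls did: 258 higher and 221 lower became 836 and 947 with the replicate block, 124 and 142 at a log2 fold change of at least 1, and 109 of 219 and 232 of 483 higher without YAPS94A-shGFP replicates 2 and 3. Under hairpin 1, 350 and 256 became 876 and 1012 with the block, and 474 of 949 higher without a filter. At that fold, 272 and 268 for hairpin 1 in the YAP line became 63 and 89, and 1087 and 996 in the YAPS94A line 297 and 379. With the replicate number as a block the counts were 1783 (construct, shGFP), 1888 and 1863 (construct under hairpins 1 and 2), 839 and 1798 (both hairpins, YAP and YAPS94A lines), 96 (interaction), and 4840 and 3714 (hairpin 2 against 1, YAP and YAPS94A lines). With the description code as a block they were 915, 1235, 1114, 479, 1177, 13, 3491 and 2404. DESeq2 called 729, 979 and 848 for the 3 construct comparisons, 331 with both hairpins in the YAP line and 20 for the interaction. Without a filter on low counts the construct comparisons called 729, 949 and 826 and the interaction 57. A log2 fold change of at least 1 left 266 (construct), 63 and 264 (both hairpins), by its own construction. Using only the groups compared gave 45 for the construct and 374 for both hairpins in the YAPS94A line, with fewer libraries to estimate the spread. limma on the deposited scaled values with a pseudocount of 1 called 1 gene for the interaction. Except where stated, the cause was not tested.

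Of the gene lists, an estimated correlation left 0 (construct), 1 and 2 (hairpins, YAP and YAPS94A lines) and 2 (interaction) past camera, against 13, 5, 15 and 14. The fry directional test passed 5 for the construct, 2 for the hairpins in the YAP line and 2 for the interaction, and its mixed test 12 and 2 for the last 2. For the hairpins in the YAP line the replicate block gave 9 and no filter 8. The overlap of construct and hairpin calls went from 16 to 9 with a fold threshold, and to 129 and 46 without shared libraries, where the hairpin list was also that of a single hairpin, so 2 choices changed at once; the cause was not tested.

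Leaving out 1 library at a time gave 132 to 532 calls for the construct, 343 to 492 and 322 to 422 under hairpins 1 and 2, 97 to 215 and 260 to 720 with both hairpins in the YAP and YAPS94A lines, 0 to 2 for the interaction, and 880 to 1911 and 424 to 1139 for hairpin 2 against hairpin 1. The line concerned then had 2 libraries, and the cause was not tested further. Of 259 calls of named genes, 149 held in each of these settings and 110 were lost in at least 1. None of these fits had the replicate block. A lost call therefore does not show that the blocked result rests on 1 library. For named genes, the replicate block left 296 values on the same side of the threshold and took 20 past it. It turned the sign of 2 that did not pass. Apart from those and the values given beside their results, it took no other list in the report across the threshold. It moved no other refitted count there by over 1.5 times, and within that bound it changed some members of lists. Genes shared between comparisons or lines were not recounted with it, except those called with both hairpins or in all 3 arms. DESeq2 left 315 on the same side and took 3 past it, its size factors left 315 and lost 3, and the 061218 libraries left 262, lost 42, took 8 past it and turned 6 that did not pass. No filter left 295, lost 7, took 15 past it and turned 1 that did not pass, and the description code as a block left 306 and took 12 past it. limma on the deposited scaled values left 306, lost 8, took 1 past it and turned 3 that did not pass at a pseudocount of 1, and left 310, lost 5 and turned 3 at 0.1. In simulated construct data at these depths, without the pairing and without a block, 12.3% of genes changed by 1.5-fold were called. In such a fit most differences of that size go undetected.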

Other observations

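The histone test and the choice of genes named for hairpin 2 against hairpin 1 in this part were made only after the results were seen; the 7-mer tests were planned.

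Hairpin 2 and hairpin 1 cells differed in matrix and inflammatory genes. THBS1 was higher with hairpin 2 by 1.39 ± 0.20 in the YAP line and 1.13 ± 0.20 in the YAPS94A line (edgeR adjusted p = 0.000406 and 0.00276). S100A7 was higher by 2.51 ± 0.63 and 3.08 ± 0.43 (0.0172 and 0.000505), and TNC, the matricellular protein tenascin-C, by 3.18 ± 0.57 and 1.85 ± 0.54 (0.00256 and 0.0494). CXCL8, a neutrophil chemokine, was higher by 2.61 ± 0.61 and 2.08 ± 0.56 (0.0128 and 0.0341). Of 25 NF-kB and inflammatory cytokine genes 6 were higher in the YAP line and 3 in the YAPS94A line (6 and 5 adjusted over the list alone, 12 and 13 with the block; median 0.42 and 0.58, camera adjusted p = 0.0155 and 0.00388; adjusted p = 0.705 and 0.512 with an estimated correlation), and none was lower, or 1 in the YAP line with the block. Extracellular matrix genes had 10 higher and 1 lower of 34 in the YAP line (15 and 2 adjusted over the list alone, 18 and 3 with the block; median 0.51, camera adjusted p = 7.43e-06) and 9 higher in the YAPS94A line (11 adjusted over the list alone, 17 with the block; median 0.51, camera adjusted p = 3.09e-07). With an estimated correlation the adjusted p was 0.164 and 0.0529, and with that correlation and the block 0.0161 and 0.00736. EREG was higher with hairpin 2 in both lines, by 0.91 ± 0.22 and 1.10 ± 0.20 (0.0137 and 0.00368), while AREG differed by −0.70 ± 0.13 in the YAP line (0.00286) and −0.03 in the YAPS94A line (0.936).

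A set for each hairpin held genes called lower with it than with shGFP, and than with the other hairpin, in both lines. Such genes could also be called lower with the other hairpin, as EREG was. The hairpin 1 set held the 7-mer GACGGAA in the 3′ UTR far more often than genes of like length. It stood in 39 of 133 genes against 3.8 expected (z = 18.57, highest among random sets 6.03). The hairpin 2 set held GTCCTCC in 50 of 90 against 12.9 expected (z = 11.63, highest among random sets 6.91). In genes chosen in the same way but higher with a hairpin, the highest z was 4.57 and 5.13, reached in 263 and 42 of 1000 random sets. Of genes with a GACGGAA site 17% were lower with hairpin 1 in the YAP line and 24.6% in the YAPS94A line, against 1.7% and 6.9% without; for GTCCTCC and hairpin 2 the shares were 8.4% and 8.5% against 2.8% and 2.7%. With the other hairpin the shares were 2.9% and 5.8% against 3.5% and 3.4% for GACGGAA, and 2.5% and 8.0% against 1.9% and 7.2% for GTCCTCC. The genes of the sets are among those counted in these shares. They made up 39 of the 47 and 68 genes called lower with GACGGAA and hairpin 1 in the YAP and YAPS94A lines. For GTCCTCC and hairpin 2 they made up 50 of 132 and 134. The sets were chosen as lower with their own hairpin, so the shares are partly built in and are no independent support. A candidate explanation is that part of the genes lower with 1 hairpin are seed matches of that hairpin, a hypothesis since both 7-mers were found on these data. The hairpin sequences are not given in the sources used here. For genes lower with both hairpins the search was void, since only 76.5% had an annotated 3′ UTR.

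The same 7-mers occur in NCOA3. Its longest coding transcript (7961 nt) holds GACGGAA 3 times, at chromosome 20 positions 47627035 to 47627041 (coding exon 6), 47636538 to 47636544 (exon 12) and 47655284 to 47655290 (3′ UTR, exon 23). It also holds GTCCTCC 3 times, at 47639041 to 47639047 and 47639095 to 47639101 (exon 14) and 47652448 to 47652454 (exon 21), all on GRCh38. Of 1554 transcripts of like length, 12.5% and 41.0% hold at least 1 copy, so the match of GTCCTCC says little. A seed match may also underlie part of the difference between the hairpins described above.

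Although the labels name a total-RNA kit, between 98.5% and 99.0% of gene reads lay in protein-coding genes, and 2.67% to 5.44% of all reads lay outside features. Replication-dependent histone genes, whose transcripts lack a poly(A) tail, had a median of 0.0848 CPM. This is consistent with reads mostly from poly(A) RNA, or with later removal of such genes, and no library was prepared another way for comparison. Mitochondrially encoded genes took 1.49% to 9.25% of gene reads, most in replicate 2 of each line, and in the YAP line with hairpin 1 their list had a median of −0.62 against shGFP (camera adjusted p = 0.0312; adjusted p = 0.753 with an estimated correlation; 0 called, 7 lower with the block). Unmapped reads made up 3.78%, 3.14% and 3.32% in the YAP-shGFP libraries and at most 2.82% in the other lines.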
